A study of Mus musculus with 7 samples.

How the data were processed

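Total RNA of naive CD8b+ CD44low OT-1 Rag-/- lymph node T cells from mice was measured on 7 single-colour (Cy3) Agilent arrays, 3 from WT and 4 from Lck-off mice, in which the inducible Lck was off after 7 days without doxycycline. Per the labels, RNA was extracted with RNeasy columns and labelled with the Low Input Quick Amp kit. The series text calls the samples biological replicates; whether each came from 1 animal, and what diet the WT mice had, is not given in the sources used here. All arrays lay on 1 slide in 2 rows: WT replicate 3 and Lck-off replicates 2 and 3 in row 1, the others in row 2.

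Per the file headers, the authors made the intensity values with Feature Extraction 10.7.3.1 on array design 028005, with probe positions on mm9: the processed intensity was background subtracted and detrended within each array, with no normalization between arrays, and the mean spot intensity and local background intensity were not corrected. Per the file headers, the other columns used, flags for spots well above background, saturated or non-uniform, and the type of spot, come from the same software. The deposited value table is in log2, a scale found from its values; the submitters' processing notes name limma without a version, and its steps are not given in the sources used here. Its columns had nearly the same distribution (medians 6.35, 6.34 and 6.34 in WT, 6.34, 6.34, 6.35 and 6.35 in Lck-off).

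Values were log2 processed intensities minus each array's 75th percentile over its non-control spots. Spots called non-uniform were set to missing, spots of a probe were averaged, and probes well above background on at least 3 of 7 arrays were kept: 25578 of 55681. Each gene name was measured by its brightest kept probe, which gave 18231 genes of 34797 names. Of these, 65.4% were matched to a current symbol through a GRCm38.p6 gene table, used for names alone. Of 427 called genes with several kept probes, 98 had a probe that changed by under 0.5 times as much or the other way. The 75th percentile of intensity was 208, 210 and 235 in WT and 221, 212, 243 and 232 in Lck-off. The median SE of a log2 difference was 0.11.

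Lck-off was compared with WT by limma 3.58.1 (R 4.3.3, the data.table package at 1.17.8) with a moderated fit to all genes and a Benjamini-Hochberg adjusted p under 0.05, two-sided; 2-fold counts were taken among these. A gene not well above background on any array of 1 group has its fold given as a lower bound, from the intensity of the faintest probe well above background on each array of that group. Named genes were chosen by a rule: Lck, the 12 largest rises and 12 largest falls among called genes with a gene symbol and no overlap between groups, and up to 4 genes of smallest p in each list; 3 genes that the rule names, and 1 further list member, are not reported here by name. The 26 gene lists, the rule, the tests and most alternatives were fixed before the data were examined. Lists with at least 5 measured genes were tested with camera from limma (preset correlation 0.01), again with an estimated correlation, and with fry, with adjustment over the 26 lists; the exact permutation test used all 35 splits of the arrays. The lists covered proximal T cell receptor signalling, activity-induced early genes, negative regulators, naive and quiescence genes, homeostatic cytokines, effector and memory genes, the type I interferon response, cell cycle, ribosome biogenesis, cytosolic ribosomal proteins, glycolysis and nutrient uptake, cholesterol and fatty acid synthesis, oxidative phosphorylation, mitochondrial ribosomal proteins, apoptosis and survival, trafficking, stress and sample handling, 8 lists of markers of other cells, and sex-linked genes. Of the marker probes on the array, 6 of 14 for B cells, 3 of 22 for macrophages, 3 of 20 for dendritic cells, 4 of 17 for NK cells, 3 of 11 for CD4 and regulatory T cells, 4 of 20 for immature thymocytes, 7 of 17 for red blood cells and platelets and 10 of 21 for stroma were not well above background on any array. Lists of MHC class I presentation genes and of small nucleolar RNA host genes were added after the data were seen.

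Alternatives were other background correction (normexp, offset 50), scalings and filters, the deposited table, all probes of a gene averaged, trended and robust moderation, array weights, blocks by replicate number or slide row, and each array left out in turn. Added after the data were seen were population outlier spots set to missing, the Xist level as a covariate, each slide row alone, and variants of the gene sets. In simulated data of the same size, 30%, 74%, 94% and 100% of genes changed by 0.5, 1, 2 and 3 were called, 8.59% of calls were false, and 0 of 25 unshifted lists were called. The simulated noise was independent between genes and the lists were random. Real genes move together (estimated correlation 0.72 in the interferon list), so these rates need not hold for the real genes and lists.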

Results

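Gene expression was measured in naive CD8 T cells taken from mouse lymph nodes, to compare WT cells with cells in which, per the labels, the tyrosine kinase Lck had been switched off. Lck phosphorylates the signalling chains of the T cell receptor and is the first kinase to act when the receptor binds its ligand. The mice carried the OT-1 receptor, a transgenic T cell receptor that recognises an ovalbumin peptide, and lacked Rag, so that no other receptors were rearranged. The WT group held 3 samples. The other group held 4 samples from mice without a working Lck gene of their own, in which an Lck copy that is on while doxycycline is given had been switched off by leaving the drug out of the diet for 7 days; it is called Lck-off here. Cells were sorted for CD8b and for low CD44. The labels give the diet change for the Lck-off mice alone, so that diet and Lck changed together. These mice also lacked a working Lck gene of their own and had relied on the inducible copy. No mice of that genotype still on doxycycline were measured. Effects of genotype, of diet and of switching Lck off therefore cannot be told apart. Each sample was hybridised to 1 array, and all 7 arrays lay on 1 slide. Between 42.5% and 48.6% of the 55681 probes were well above background on an array, the 75th percentile of intensity lay between 208 and 243, and no spot was saturated. Pearson's r across genes was 0.990 to 0.995 between arrays of the same group and 0.983 to 0.987 between arrays of different groups, where genes are not independent replicates. The number of arrays limits the precision of every value. Levels are log2 intensities relative to the array's 75th percentile, ± is the SD over 3 WT or 4 Lck-off arrays, and differences are Lck-off minus WT on the log2 scale.

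Lck RNA was lower in Lck-off cells, at 77.2% of the WT level (95% confidence interval 66.6% to 89.4%). Lck fell by 0.37 (SE 0.09, adjusted p = 0.0493 by limma; exact permutation, two-sided, 2 of 35 splits, p = 0.0571), to 8.62 ± 0.14 in Lck-off. The WT arrays read 8.99, 9.02 and 8.98 for Lck, and the Lck-off arrays read 8.52, 8.83, 8.60 and 8.55, all below the lowest WT array. The array holds 1 Lck probe, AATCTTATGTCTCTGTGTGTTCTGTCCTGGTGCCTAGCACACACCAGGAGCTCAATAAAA, on the minus strand of chromosome 4 from 129225614 to 129225673 (mm9), starting at base 2085 of the transcript. The labels do not say which part of Lck was disrupted or whether the inducible copy carries this stretch, so the probe may lie outside the altered part and then checks nothing. The call ended in 6 of the 7 repeats that left out 1 array (adjusted p = 0.0149 to 0.154 over the 7), and with the slide row as a block (adjusted p = 0.0583). The difference was -0.27 within row 1 of the slide and -0.47 within row 2.

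All 40 measured genes of the type I interferon response rose, with a median of 1.68, among them the antiviral GTPase gene Mx1 (4.52 ± 0.25 SE) and Ly6a, the surface antigen Sca-1 (3.86). As a list they were not called with an estimated correlation (adjusted p = 0.341 with an estimated correlation). Macrophage and dendritic cell markers were also higher in Lck-off as list medians (0.59 and 0.86), though not each marker on every array. CD5 and CD6, inhibitory partners of the T cell receptor, fell by 1.12 and 0.91, from a stretch of chromosome 19 (10 to 20 Mb) where 16 of 75 genes changed, and so did the effector transcription factor Tbx21 (T-bet, -0.95). Of the genes of the cell cycle and of lipid synthesis, 5 of 27 and 10 of 26 fell, among them Stmn1 (-1.87) and the sterol demethylase gene Cyp51 (-1.14); as lists they were called by camera at its preset correlation, but not with an estimated correlation (adjusted p = 0.369 and 0.341 with an estimated correlation). Of 18231 genes tested, 1527 changed at an adjusted p under 0.05 by limma, 693 higher and 834 lower in Lck-off, and 441 of them changed at least 2-fold (227 higher, 214 lower). All 1527 had no overlap between the arrays of the groups. Over all genes 21.8% had none, where chance gives 5.71%. The count was 960 without WT replicate 2, 984 without WT replicate 3, 964 without Lck-off replicate 3 and 968 without Lck-off replicate 4. Genes higher numbered 449 without Lck-off replicate 3, and genes lower 540, 473 and 504 without WT replicates 1, 2 and 3 and 515 and 497 without Lck-off replicates 3 and 4. The 2-fold count was 216 with normexp background correction and 213 with the authors' deposited table. With the slide row as a block 1304 genes changed; within row 1 (1 WT and 2 Lck-off arrays) 105 did, and within row 2 (2 and 2) 0 did by limma, with 2711 genes there at an unadjusted p under 0.05.

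Among the 12 largest measured rises, 6 were classical interferon-induced genes: Ifi44, Mx1, Oas1a (4.17), Oas2 (3.81), Ifit3 (3.68) and Usp18 (3.50). Ifi44 was not well above background on any WT array and was at least 21.6-fold higher in Lck-off. Ly6a and Ly6g (3.71) were also among them, but members of the Ly6 family are close in sequence and can cross-hybridise. Rbbp9 (at least 6.92-fold), Csprs (3.97) and Vwce (at least 5.87-fold) were among them too. Rbbp9 and Vwce were not well above background on any WT array, and at their bounds they rose by less than Mx2 (3.11), which is not among the 12. For Rbbp9 and Csprs another probe of the gene changed by under 0.5 times as much or went the other way. The largest measured fall was that of Rab6b, a Golgi trafficking GTPase, by 6.65, with 3 of 3 WT and 2 of 4 Lck-off arrays well above background. Wdr95 fell by 3.75, Srgap3 by 3.13, Leprel4 (now P3h4) by 3.00, Gabrd by 2.86, Trnp1 by 2.53 and the sodium-calcium exchanger gene Slc24a3 by 2.40. Srgap3 and Gabrd were well above background on 2 and 1 of the 4 Lck-off arrays. Stk3, Susd4, Esrp2, Itih5 and Padi3 were not well above background on any Lck-off array, and were at least 5.59-fold, 3.45-fold, 2.64-fold, 2.59-fold and 1.82-fold lower there. Esrp2 lost its call in 4 of the 7 repeats with 1 array left out (adjusted p up to 0.0806), and Srgap3 without WT replicate 3 (adjusted p = 0.0521).

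**Figure D1:**
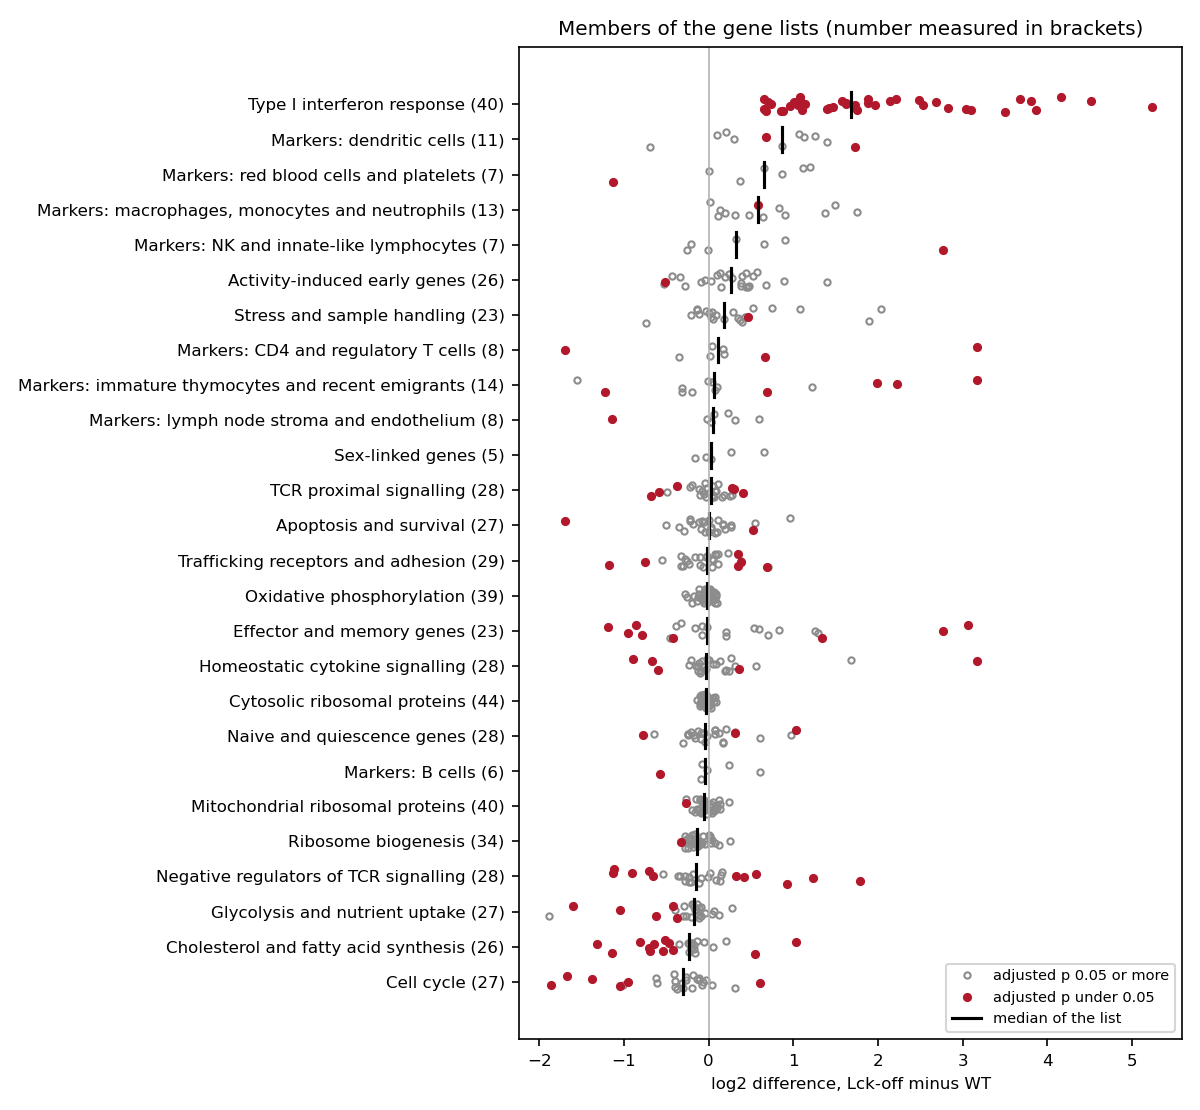
Log2 difference (Lck-off minus WT, horizontal axis) of each measured member of the 26 gene lists, with the number measured in brackets. Filled red points passed an adjusted p of 0.05, open points did not, black bars are list medians, and members not well above background are drawn at their measured value; all 40 interferon genes lie above 0, and the cell cycle list has the lowest median, -0.31.

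The type I interferon response was the clearest group difference. All 40 measured genes of this list rose, 40 of 40 also when adjusted over the list alone, with a median of 1.68, or 3.21-fold. Mx1 went from -0.05 ± 0.52 in WT to 4.47 ± 0.26 in Lck-off, Mx2 rose by 3.11, the exonuclease gene Isg20 by 2.15, and Bst2 (tetherin, which holds budding virus at the cell surface) by 1.73. On the 75th-percentile scale the list's median per array was 2.52, 3.20 and 2.69 in WT and 4.75 to 5.03 in Lck-off. The list was shifted against other genes by camera (adjusted p = 1.42e-44). Its members moved so closely together that the call was lost when this was allowed for, with an adjusted p = 0.341 with an estimated correlation; fry, which tests the list's own genes, gave an adjusted p of 0.00129. The real grouping gave the largest median of the 35 ways to split the arrays (exact permutation p = 0.0286, two-sided, the smallest these splits can give, and 0.186 adjusted over 26 lists). With the slide row as a block the median was 1.69, and within rows 1 and 2 it was 1.67 and 1.72. Macrophage and dendritic cell markers were also higher in Lck-off, with list medians of 0.59 and 0.86. Not each marker was higher on every Lck-off array: H2-Ab1 was 0.02 on Lck-off replicate 4 and 0.64 on WT replicate 2. The median over 23 of these markers was higher on each Lck-off array than on any WT array (-0.75 to 0.20 against -1.28 to -0.87).

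**Figure D2:**
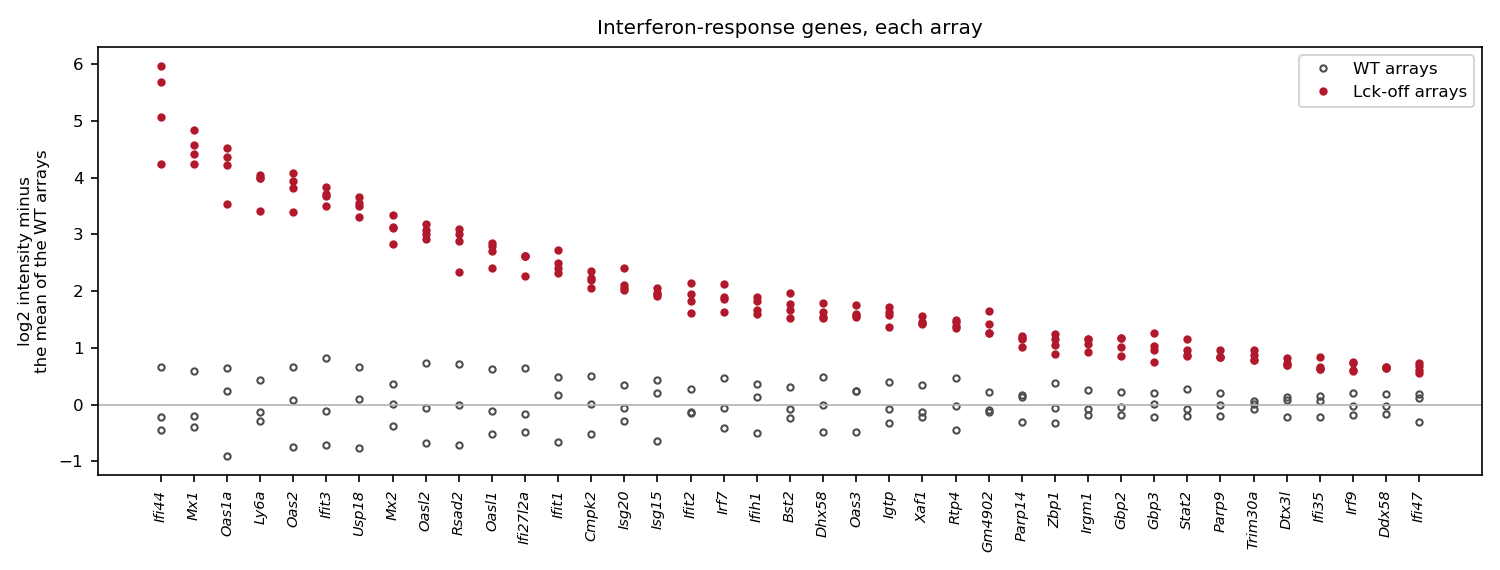
Log2 intensity of 39 of the 40 interferon-response genes on each array (vertical axis), relative to the mean of the WT arrays. Open circles are the 3 WT arrays and filled circles the 4 Lck-off arrays; for every gene shown all Lck-off arrays lie above all WT arrays, from Mx1 (4.52) to Ifi47 (0.65) among genes well above background in both groups, while Ifi44 was not in WT (at least 21.6-fold higher in Lck-off).

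Some genes of proliferation and of lipid synthesis were lower in Lck-off cells, while most members of these lists did not pass the test. Neither list was called when the correlation between its genes was estimated (adjusted p = 0.369 and 0.341 with an estimated correlation). Of 27 measured cell cycle genes 5 fell, 1 rose and 21 did not pass, with 11 falling when adjusted over the list alone. Stmn1, which destabilises microtubules in dividing cells, fell by 1.87 with 1 of its probes disagreeing, Uhrf1, which maintains DNA methylation at replication, by 0.96, and Birc5 (survivin) by 1.05. Top2a, the topoisomerase of dividing cells, was at least 2.03-fold lower and not well above background in Lck-off. Of 26 cholesterol and fatty acid synthesis genes 10 fell and 2 rose (11 and 2 adjusted over the list alone): the isoprenoid enzyme gene Idi1 fell by 0.81, Cyp51 by 1.14 and the fatty acid elongase gene Elovl6 by 0.69. Of 27 glycolysis and nutrient uptake genes 5 fell and 0 rose (7 and 0 adjusted over the list alone): the aldolase gene Aldoc fell by 1.60, the lactate exporter gene Slc16a3 by 1.05, Tpi1 by 0.42 and the glutamine transporter gene Slc38a1 by 0.37. The last 2 each lost their call in 3 of the 7 repeats with 1 array left out (adjusted p up to 0.0616 and 0.0516). Of 34 ribosome biogenesis genes only Gar1 passed the test (-0.33), also when adjusted over the list alone, and it lost its call in 5 of 7 such repeats (adjusted p up to 0.0678).

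List medians were -0.31 for the cell cycle, -0.23 for lipid synthesis, -0.17 for glycolysis and -0.14 for ribosome biogenesis, and all 4 lists were shifted down by camera (adjusted p = 7.04e-06, 7.32e-06, 0.000163 and 0.0051). With an estimated correlation none held: adjusted p = 0.369, 0.341, 0.390 and 0.912 with an estimated correlation, in the same order. Exact permutation of the 7 arrays gave 1, 1, 3 and 3 of 35 splits with a median as large (p = 0.0286, 0.0286, 0.0857 and 0.0857, two-sided). The ribosome biogenesis list was no longer called without WT replicate 3 (adjusted p = 0.156) or within row 2 of the slide (adjusted p = 0.169). With the slide row as a block the medians were -0.32, -0.22, -0.17 and -0.16; within row 1 they were -0.26, -0.37, -0.29 and -0.23, and within row 2 -0.27, -0.24, -0.15 and -0.12. Myc, the growth-promoting transcription factor, did not pass the test (-0.53, adjusted p = 0.0528). The bulk machinery of protein synthesis and respiration showed little difference: 0 of 44 cytosolic ribosomal protein genes and 0 of 39 oxidative phosphorylation genes passed by limma (0 and 0 adjusted over the list alone; 0 and 3 at an unadjusted p under 0.05; camera adjusted p = 0.565 and 0.489). The nearest to passing in the respiration list was Cox6c (-0.28, adjusted p = 0.0576). Of 40 mitochondrial ribosomal protein genes 1 fell (Mrps28, -0.27; 0 adjusted over the list alone; camera adjusted p = 0.431), and it lost that call in 7 of 7 repeats with 1 array left out.

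Genes that restrain T cell receptor signalling went both ways. Of 28 measured negative regulators 6 rose and 5 fell (6 and 10 adjusted over the list alone). Cd5 went from 7.28 ± 0.03 in WT to 6.17 ± 0.08 in Lck-off and Cd6 from 7.67 ± 0.01 to 6.76 ± 0.08, while the cytokine-induced inhibitors Cish and Socs1 rose by 1.79 and 1.24. Of 28 genes of proximal receptor signalling 3 rose and 3 fell (4 and 4 adjusted over the list alone). The phosphatase gene Ptpn6 (SHP-1) fell by 0.68 and Rasgrp1, which activates Ras, by 0.58, while the adaptor gene Grap2 rose by 0.40. These 3 calls ended in 2, 6 and 6 of the 7 repeats with 1 array left out (adjusted p up to 0.0655, 0.0927 and 0.114). Of 26 activity-induced early genes only the AP-1 member Fosl2 changed, lower by a log2 difference of -0.52, also when adjusted over the list alone. None of these 3 lists was shifted by camera (adjusted p = 0.431, 0.914 and 0.489), although the list of activity-induced early genes was without Lck-off replicate 1 (adjusted p = 0.0480; with all arrays, adjusted p = 0.972 with an estimated correlation).

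Effector genes also split. Of 23 measured effector and memory genes 3 rose and 5 fell (5 and 6 adjusted over the list alone, camera adjusted p = 0.914). Ly6c1, a surface marker of memory CD8 cells in the cross-hybridising Ly6 family, rose by 3.06 and the granzyme gene Gzma by 2.77. Tbx21 went from 1.51 ± 0.13 to 0.56 ± 0.15 and the cytotoxic granule gene Nkg7 from 8.12 ± 0.05 to 7.34 ± 0.10. Eomes, the partner of T-bet, fell by 0.86 and Cd44 itself by 1.18, both chosen after their values were seen. Of 28 homeostatic cytokine genes 2 rose and 3 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.914). The IL-2 receptor alpha chain gene Il2ra was at least 7.14-fold higher and not well above background in WT, while the beta chain gene Il2rb fell by 0.60, Il6st by 0.67 and the kinase gene Pim2 by 0.89. Il2rb and Il6st lost their calls in 4 and 5 of the 7 repeats with 1 array left out (adjusted p up to 0.0608 and 0.0601).

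**Figure D3:**
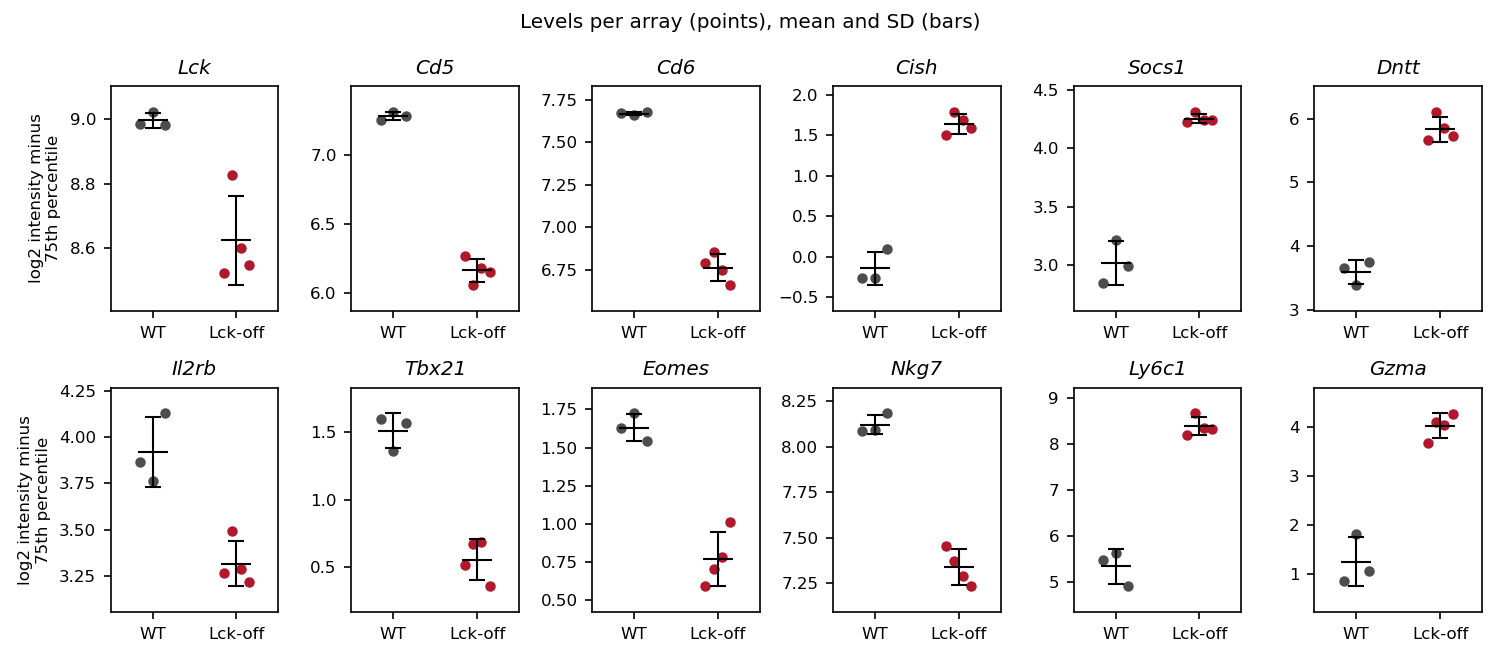
Log2 intensity minus the array's 75th percentile (vertical axes, one scale per gene) of 12 named genes on the 3 WT (grey) and 4 Lck-off arrays (red); bars give the mean and SD. Cd5, Cd6, Il2rb, Tbx21, Eomes and Nkg7 lie lower and Cish, Socs1, Dntt, Ly6c1 and Gzma higher in Lck-off, with no overlap between groups; Lck differs by -0.37.

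Of 28 naive and quiescence genes 2 rose and 1 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.914). Slfn2, which keeps T cells quiescent, rose by 1.04, the cell cycle inhibitor gene Cdkn1b by 0.31, and Dapl1 fell by 0.77. Of 29 trafficking genes 4 rose and 2 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.914): P2rx7, the ATP-gated channel gene, fell by 1.17, the chemokine receptor gene Cxcr6 by 0.75, and the gut-homing receptor gene Ccr9 and Ltb (lymphotoxin beta) rose by 0.69 and 0.35. Of 27 apoptosis and survival genes Bbc3 (Puma, which promotes cell death) fell by 1.70 and Bcl2l1, whose main product Bcl-xL protects cells, rose by 0.53 (1 rose and 2 fell adjusted over the list alone, the list not called by camera). Of 23 stress and handling genes only Txnip rose (0.47, also when adjusted over the list alone, camera adjusted p = 0.149). Cdkn1b, Ltb, Bcl2l1 and Txnip lost their calls in 7, 6, 6 and 2 of the 7 repeats with 1 array left out (adjusted p up to 0.106, 0.0742, 0.121 and 0.0547). The stress and sample handling list was shifted up without WT replicate 3 (adjusted p = 0.0497) and without Lck-off replicate 1 (adjusted p = 0.00952), and the list of cytosolic ribosomal proteins down without WT replicate 3 (adjusted p = 0.0497). With all arrays these lists had adjusted p = 0.955 and 0.972 with an estimated correlation. The median, the mean and the direction of camera did not share a sign for the lists of proximal receptor signalling, naive genes, homeostatic cytokines, effector genes, apoptosis and B cells.

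A few markers of macrophages and dendritic cells rose in the Lck-off samples, and most did not pass the test. Lck-off replicate 2 stood apart on several: H2-Ab1 was 2.25 there against 0.96, 0.81 and 0.02 on the other Lck-off arrays, Fcer1g 0.20 against -0.80, -0.84 and -1.44, and the neutrophil gene S100a9 was well above background on that array alone. Without Lck-off replicate 2 the list medians were 0.49 for macrophages, monocytes and neutrophils and 0.75 for dendritic cells, called by camera at its preset correlation (adjusted p = 0.00205 and 0.0107). With all arrays neither list was called when the correlation was estimated (adjusted p = 0.478 and 0.478 with an estimated correlation). Of 13 measured macrophage, monocyte and neutrophil markers the complement gene C1qb rose (0.59) and 12 did not pass (4 rose adjusted over the list alone), with C1qa at 1.38, C1qc at 1.75 and Mpeg1 at 1.49. Of 11 dendritic cell markers Bst2, which is also in the interferon list, and Tcf4 (0.68) rose (2 adjusted over the list alone; median 0.77 and camera adjusted p = 0.0304 without Bst2), and the MHC class II gene H2-Ab1 did not pass (1.40, adjusted p = 0.223). Both lists were shifted up by camera (adjusted p = 0.000882 and 0.00399), but with adjusted p = 0.478 and 0.478 with an estimated correlation, and neither was within row 2 of the slide (medians 0.34 and 0.51, adjusted p = 0.0554 and 0.0942), against medians of 0.86 and 0.86 within row 1 and 0.54 and 1.06 with the row as a block. C1qb and Tcf4 each lost their call in 6 of the 7 repeats with 1 array left out (adjusted p up to 0.144 and 0.106). C1qb lies within 10 Mb of Lck and Tcf4 between 60 and 70 Mb of chromosome 18, regions rich in changed genes. Their values are not separated from a difference in these regions. The T cell genes Cd8a, Cd8b1 and Cd3e differed by 0.28, 0.25 and -0.04 and did not pass (adjusted p = 0.146, 0.065 and 0.801).

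The remaining marker lists were not shifted by camera. Among 14 markers of immature thymocytes and recent emigrants (camera adjusted p = 0.151) 4 rose and 1 fell (5 and 2 adjusted over the list alone): Dntt, the terminal transferase of developing lymphocytes, rose by 2.23, Ccr9 and Il2ra rose as above, Ly6d was at least 3.66-fold higher, and Sox4 fell by 1.22. In the list of CD4 and regulatory T cells (8 measured, camera adjusted p = 0.317) Trat1 rose by 0.66, Il2ra rose and Ikzf2 (Helios) fell by 1.70, with 2 rising and 2 falling adjusted over the list alone. The NK list (7 measured, camera adjusted p = 0.165) had 1 rise, Gzma (2 adjusted over the list alone). In the lists of B cells (6 measured), red blood cells and platelets (7) and stroma (8) 1 gene each fell, also when adjusted over the list alone: Pou2af1 (-0.57), Car2 (-1.13) and Pdgfrb (at least 1.60-fold lower); camera gave adjusted p = 0.916, 0.839 and 0.912. Ikzf2 and Pdgfrb lost their calls in 6 and 6 of the 7 repeats with 1 array left out (adjusted p up to 0.112 and 0.129). Of 5 sex-linked genes 0 passed by limma (0 also adjusted over the list alone, and 0 at an unadjusted p under 0.05), and camera did not call the list. Xist was below -5 on WT replicate 1 and Lck-off replicate 1 and above 0 on the other arrays, so that each group held both sexes.

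Changed genes were more frequent around the Lck gene itself. Within 10 Mb of the Lck probe on chromosome 4, 64 of 316 genes changed (20.3%), against 1428 of 17709 elsewhere (8.06%), an odds ratio of 2.90 (95% confidence interval 2.15 to 3.85, Fisher's exact test, two-sided, p = 1.50e-11). The odds ratio was 2.15 at 10 to 20 Mb, 1.09 at 20 to 40 Mb and 0.77 beyond 40 Mb on the same chromosome, and it was 3.12 for genes that fell and 2.19 for genes that rose. Among those nearby, chosen after their values were seen, the heparan sulphate proteoglycan gene Sdc3 rose by 2.95 and E2f2 by 1.67, Zbtb8a fell by 2.30 and Fgr, a kinase gene of the Src family, by 1.08. Fam167b, the changed gene nearest to the Lck probe other than Lck, was at least 2.84-fold higher, and Marcksl1 rose by 0.83. Trnp1, Stmn1 and C1qb also lie within these 10 Mb. Within row 1 of the slide the odds ratio was 2.95, with the row as a block 2.80, and row 2 alone had no changed gene to count.

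**Figure D4:**
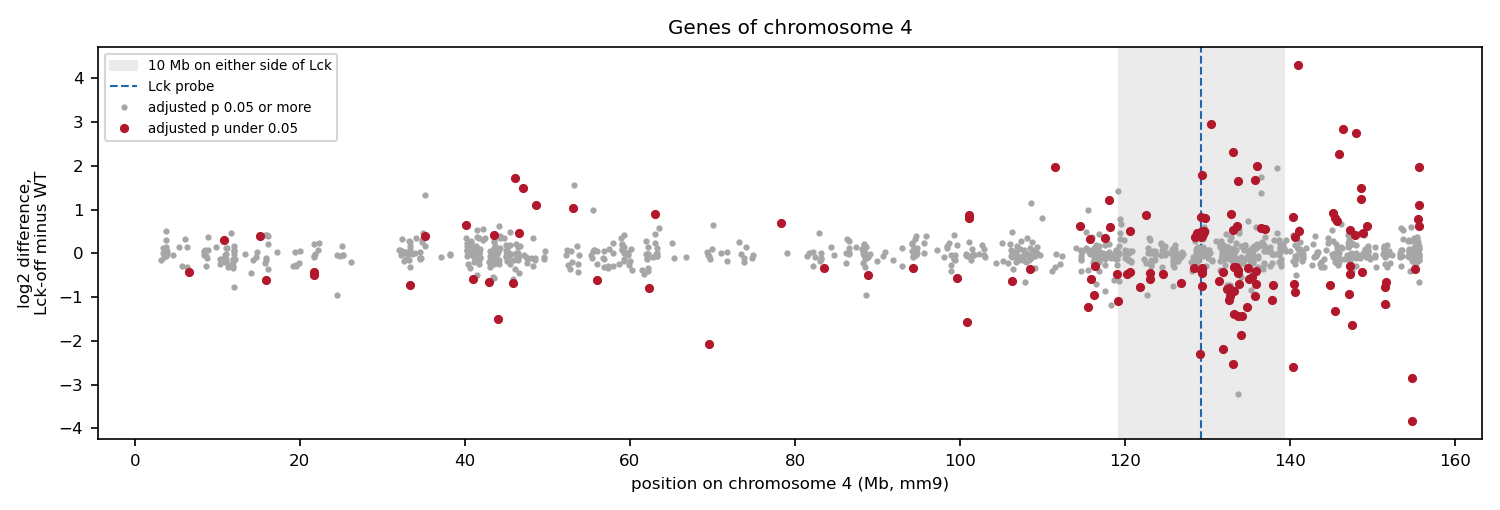
Log2 difference (Lck-off minus WT, vertical axis) of the genes of chromosome 4 against position (Mb, mm9). Red points passed an adjusted p of 0.05, grey points did not; the dashed line marks the Lck probe and the shaded band the 10 Mb on either side, where 64 genes other than Lck passed.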

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

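The tests of scaling, of transcripts abundant in macrophages or dendritic cells, and of immature thymocytes were chosen only after the result was seen. Of the 35 splits of the 7 arrays, 1, the real one, gave as many changed genes (1527, highest other 7) or as many 2-fold changes (441, highest other 7). The real grouping thus stood apart for these counts, but 1 of 35 is the smallest share these splits can give. Every other split also mixes the groups. For the number of shifted lists the real grouping did not stand apart: 8 of the 35 splits gave 7 or more, with a highest other of 10.

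Interferon-response genes were higher in every Lck-off array. Scaling between arrays is argued against, since the list's lowest median under 5 other scalings was 1.59. DNA of another strain near the altered loci is argued against only as a local difference at the interferon genes themselves. Members outside the 9 windows rich in changed genes had a median of 1.62 over 14 chromosomes. An effect of such DNA on interferon genes elsewhere was not tested and would give the same values. RNA of macrophages or dendritic cells, carried along in the sort or from a larger share of unchanged cells, stays open as a direct source of the rise. Of 40 interferon genes, 35 rose by more intensity than the whole signal of any of 12 chosen transcripts of such cells on any Lck-off array. That signal was at most 4.90 (H2-Eb1, Lck-off replicate 2, where the array's 75th percentile is 1), against a median interferon rise of 15.99. Ifi44, Ifit2, Gbp3 and Ifih1 were among the 5 that rose by less than 4.90. Other members of the marker lists were brighter, such as Csf3r and Siglech (log2 means 7.69 and 8.10 in Lck-off, 7.59 and 8.00 in WT). Both were nearly as bright in WT, so their brightness does not show more RNA of such cells in Lck-off. Intensities of different probes are also not on 1 scale, so the comparison holds for the 12 alone and cannot decide. Comparing marker medians between pairs of arrays, the test chosen before the result was seen, could not decide either. In 0 of 12 pairs was the median of 23 markers higher in WT. Over the 14 of these well above background on every array it was in 1 pair (WT replicate 2, Lck-off replicate 4, -0.56). There the interferon median was 1.83 higher in Lck-off. The interferon difference was the larger in 10 of 12 pairs, and in 12 as a median of gene differences (by at least 0.70). Pairs share arrays, and the 14 include Csf3r and Siglech, which hardly differed, so this cannot decide. An interferon response of the T cells themselves may be an explanation, with interferon from any source, but genotype, diet and the loss of Lck changed together in this design.

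Changed genes were concentrated within 10 Mb of Lck. Interferon-response genes lying there are argued against, since 0 of the 40 lie within these 10 Mb, and genes that fell had an odds ratio of 3.12. DNA of another mouse strain kept around the targeted gene may be a source and stays open: the odds ratio of 2.90 near Lck is the pattern itself, and its fall to 0.77 beyond 40 Mb would also come from an effect limited to the region. Sequence differences under single probes stay open. Near Lck 48% of called genes with several probes had a disagreeing probe (12 of 25), against 86 of 402 elsewhere (Fisher's exact test, p = 0.00522). The share near Lck was thus higher than elsewhere, but lay between the bounds set for either outcome. An effect of Lck loss on nearby genes was not tested, so that values of Sdc3, Stmn1, C1qb and others in this stretch may not reflect loss of Lck.

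Dntt and Il2ra, genes of immature T cells, were higher in Lck-off. A larger share of immature thymocytes or recent emigrants stays open: Sox4 fell by 1.22, against it, but Cd24a did not pass (-1.55, adjusted p = 0.0647). A part in the interferon response could not be tested, since the interferon medians of the 4 Lck-off arrays spanned only 0.28. No biological explanation beyond the group itself was tested.

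In 10 of 139 groups of 4 Lck-off values 1 array lay far from the other 3, where chance gives about 1 in 20: on replicate 1 Ly6a (5.79), Kdm6a (0.70), Xist (-5.52) and H2-K1 (9.58), on replicate 2 Rpl3 (9.78), Hba-a1 (1.30), Hba-a2 (3.44), Atp5a1 (6.87) and Snhg3 (1.57), and on replicate 4 Srgap3 (-5.58). Xist and Kdm6a on replicate 1 go with the animals' sex, since both were also lowest on WT replicate 1, where Y-linked probes were high too; the other 8 were not weighed.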

How the results depend on the processing

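Population outlier spots, the Xist covariate, each slide row alone and lists without interferon genes were chosen only after the results were seen. No gene or list past the threshold changed sign (some that did not pass, with differences near 0 or a wide spread, did), but the balance of falls and rises among changed genes did: rises outnumbered falls in row 1, with either replicate number as a block, and without WT replicate 1 (547 higher, 540 lower) or 2 (487 and 473). Over the 137 named genes, 3401 comparisons with alternatives gave 2956 with the call kept or still absent, 387 with a call ended, 58 with a call gained and 0 reversed; 49 of the 92 called genes passed in every alternative chosen before the data were seen that used all arrays, and 71 with each array left out.

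Without a filter on dim probes 717 genes changed (358 higher, 359 lower; 672 shared), with 34797 names tested. With the titles' replicate numbers as a block 374 changed (193 higher, 181 lower, 284 at least 2-fold; 357 shared), and with the number in the file names 651 (326 and 325; 601 shared). Arrays of the same title number deviated little alike from their group means (r across genes 0.11, 0.05 and -0.01, against -0.17 to 0.14 over all pairs). WT replicate 1 and Lck-off replicate 1 were of the same sex by Xist, so a pairing is not excluded. An array alone in its block adds nothing to the group difference. With title numbers this was Lck-off replicate 4, and Lck was -0.35 both with this block and without that array. With file numbers it was Lck-off replicate 1, with -0.34 both ways for Lck. Blocks also leave less information for estimating the spread, and the share of each in the lower counts was not tested. Row 1 of the slide alone gave 105 (85 higher, 20 lower, 105 at least 2-fold), its lone WT array being assumed to vary like the others, and row 2 alone 0 by limma (0 higher, 0 lower, 0 at least 2-fold), with fewer arrays. Row 2 had no call from which to count genes near Lck, whose odds ratio was 1.94 to 3.46 elsewhere. The 2-fold count was 216 with normexp and 213 with the deposited table; the cause was not tested.

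Of 7 shifted lists, 0 were called with an estimated correlation and 6 lists with fry, where ribosome biogenesis and both marker lists were lost and NK and immature thymocyte markers gained. Of 2 marker lists, 0 were called with an estimated correlation and 0 in row 2.

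Lck lost its call without the filter (-0.37, adjusted p = 0.215), with blocks by title number (-0.35, 0.234), file number (-0.34, 0.212) or row (-0.39, 0.0583), with the Xist covariate (-0.38, 0.0690), and in row 1 (-0.27, 0.641) and row 2 (-0.47, 0.151).

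With each array left out, counts ranged from 960 to 1405 for genes changed, 449 to 646 higher, 473 to 759 lower, and Lck from -0.44 to -0.34. Dim signals limit which probes could be tested, since at most 48.6% of probes were well above background on an array.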

Other observations

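The test of small nucleolar RNA host genes was chosen only after the result was seen. Of 20 measured MHC class I presentation genes 13 rose and 0 fell, with a median of 0.44 (H2-T24 1.16, H2-Q7 0.64, H2-K1 0.55, H2-D1 0.47, all chosen after their values were seen). Camera in limma gave p = 0.0193 with an estimated correlation, not adjusted over lists, for a list added after the data were seen. Before adjustment camera with an estimated correlation gave p = 0.0262 for the interferon list and 0.0149 for lipid synthesis. Neither was called after adjustment (adjusted p = 0.341 for both with an estimated correlation). Of the 13 that rose, 10 lie between 30 and 40 Mb of chromosome 17; of the 7 members elsewhere 3 rose (median 0.30), so that a joint rise is not separated from a difference in this region. Of 10 small nucleolar RNA host genes 0 rose and 2 fell (median -0.14): Gas5 (-1.08, with a disagreeing probe) and Snhg3 (-2.19). Snhg3 lies within 10 Mb of Lck, so its value may not reflect loss of Lck. For this list p was 0.270 with an estimated correlation in camera from limma, so a joint fall is not shown.

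Of 245 windows of 10 Mb, 9 held more changed genes than chance gives after adjustment. Apart from 3 on chromosome 4, they were the first 10 Mb of chromosome 14 (12 of 33 genes, all 12 lower), 30 to 40 Mb of chromosome 17 (41 of 248, 33 of them higher), which holds Ltb and the MHC genes above, 170 to 180 Mb of chromosome 1 (20 of 88), 10 to 20 Mb of chromosome 19 (16 of 75), which holds Cd5, Cd6 and Vwce, 30 to 40 Mb of chromosome 19 (12 of 51), which holds Ifit3, and 60 to 70 Mb of chromosome 18 (15 of 76), which holds Tcf4 and Pdgfrb. A difference in DNA of these regions was not tested, so the values of these genes are not separated from it.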
